A study of Homo sapiens with 154 samples.

How the data were processed

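Cells from bronchoalveolar lavage were spun down and stored in Trizol, and total RNA was extracted and hybridised when its RNA integrity number was above 7, per the labels' protocols, with 50 ng of RNA as input. Each of the 154 arrays was scanned in 1 colour. Per the labels the array was the 4x44K v2 whole-genome design, while per the file headers the layout was 014850. Both are given because they name different designs. The deposited scanner files hold intensity values on a linear scale made by Agilent Feature Extraction 10.7.3.1, per the file headers, with the processed signal already corrected for background by that program. The other columns used, also per the file headers, were the deposited flags for control spots, outlier spots, saturation and signal well above background. Each array had 45015 spots, of which 43376 were not controls, and these held 41000 probes. No spot was saturated and 0.169% were marked as outliers. The authors' deposited value table holds processed values of the same arrays, which lie on a log2 scale as judged by their relation to the scanner signals. How the authors scaled or centred these values is not given in the sources used here. Their column medians lay between 7.43 and 7.69.

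Probes were named by matching the accession in the scanner files, without its version, to a RefSeq gene table of assembly GRCh38.p14, used for names only. This gave 1 symbol for 26222 probes and none for 14778, which were not analysed by gene, and 17721 genes had a probe. No coordinates are reported. XIST, TSIX and Y-linked genes (65 probes) were left out of every table.

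The main values were log2 of the processed signal over the 75th percentile of the same array, with control and outlier spots left out and the spots of a probe averaged. Each gene was represented by its brightest probe among those well above background on at least 38 arrays, the size of the smallest group, which left 14479 genes from 21260 probes. Of these genes 5090 had several tested probes. Among the changed genes with several probes, 6 of 206 in severe asthma against control, 8 of 65 in mild-moderate asthma against control and 39 of 341 in severe against mild-moderate asthma had a probe of opposite sign, and 0 had a limma call of opposite sign. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) in 1 model over the 3 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 changes are moderated standard errors. The number of arrays limits the precision of each value.

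Each of 39 gene lists, fixed with the tests, the alternatives and the rule for named genes before the data were examined, was tested by the difference of donor means over its measured members. The test was a two-sided permutation test with 100000 resamples, adjusted over 117 tests, and the smallest p it can give is 1e-05. The lists held 633 genes, of which 88.2% were tested. A test of the same lists against all other genes (camera) was run with a preset correlation of 0.01 and with an estimated one. With the preset correlation it called 13, 5 and 12 lists in the 3 comparisons, taken as severe against control, mild-moderate against control and severe against mild-moderate. With the estimated correlation it called 1, 0 and 0, and the 1 was the cyclic AMP list. Beside such counts of 0 among lists stand 1748 and 3300 genes that limma placed at an unadjusted p under 0.05. A donor counted as showing a direction when its value lay on that side of the median of the other group.

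Genes named in the text were the 8 largest increases and 8 largest decreases among the calls of a comparison, up to 4 members by p of each list described, and a panel of 15 genes fixed in advance. The ranking by size left out uncharacterised symbols, X-linked genes that escape inactivation, and immunoglobulin or T cell receptor segments. RGS2, SLA and the genes of the groups that open the other observations were chosen after their values were seen, as was the choice of which named genes to print.

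The scan date in the headers gave 14 scan days in 3 campaigns. Slides numbered 92, of which 59 held at least 2 arrays and 38 more than 1 group, and the correlation within a slide was 0.225. Each alternative was run by itself against the main values. They were normexp background with quantile normalization, which changes the background, the scaling and the signal column together, the authors' values, no or a stricter filter on dim probes (17671 and 13706 genes), leaving out 18 arrays whose median correlation with the others lay more than 3 median absolute deviations low, the marker means of pan-epithelial cells, neutrophils, eosinophils and T cells as 4 covariates, the campaign, scan day, array position, slide or replicate number as a block, every probe tested, array weights, only the 2 groups compared, and a 1.5-fold minimum. Normexp was run on the median spot signal, because the mean signal is not among the columns used here. Alternatives added after seeing the data left out campaign 3, 1 array of the closest pair of severe arrays, or the 5 columns of the authors' table that followed their own scanner file poorly (r of at most 0.639, against at least 0.831 for the other 149), or took the campaign and the number of detected probes as covariates. The median log2 change of all genes had a size of at most 0.02 in the main values and under both other scalings, with its sign turned in 2 comparisons by the authors' values.

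The limma fits were tested on simulated data with known changes. These values were normal and independent between genes, with the same spread in all groups and no campaign or slide effect. The rates may therefore not hold for the real data. For severe asthma against control, over 14479 genes, 34.3%, 74.6% and 95.5% of changes of 0.25, 0.5 and 1 log2 were recovered with 7 false calls, and for severe against mild-moderate asthma 44.8%, 79.1% and 98.5%, also with 7. A list shift of 0.3 in severe asthma against control was found in 70% of runs before adjustment, and 5.29% of unshifted lists had a p under 0.05. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps. In the comparison of alternatives, counts of changed genes are given as a percentage of the genes tested, a unit chosen after the results were seen.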

Results

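Bronchoalveolar lavage washes out the cells that lie on the surface of the small airways and alveoli, chiefly alveolar macrophages, with lymphocytes, granulocytes and shed epithelial cells. RNA of these cells was measured on single-colour Agilent whole-genome arrays, 1 array per sample, in 38 controls, 72 samples of mild-moderate asthma and 44 of severe asthma. The labels call the samples of a group biological replicates, and each was taken as 1 donor. Between 18147 and 37943 probes per array were well above background. The quality result of the array was in range for 27 of 38 control, 43 of 72 mild-moderate and 30 of 44 severe arrays. No alternative left out the arrays outside that range, so their influence as a set was not tested. The arrays fell into 3 scan campaigns that each held all groups, with 9 controls, 17 mild-moderate and 9 severe samples in the first, 19, 26 and 21 in the second, and 10, 29 and 14 in the third. In the third campaign the median signal of the negative control spots was 129, against 27.5 and 20.6 in the others, and a median of 25699 probes per array was well above background, against 32317 and 31754. The campaign accounted for 7.45% and the disease group for 1.80% of the variance of the median gene. All levels are log2 signals relative to the 75th percentile of their array, so each change is relative to the other transcripts of the same sample.

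Lavage cells of severe asthma were first set against those of controls, to ask which genes differed between the most severely affected donors and donors without asthma. Genes that cyclic AMP switches on through the transcription factor CREB fell as a group, by a mean log2 difference of -0.56 ± 0.10 (SE, n = 44 and 38, 95% interval -0.76 to -0.36), and 39 of 44 severe donors lay below the control median. Of its 23 measured members 12 fell and none rose, and 12 also fell when adjusted over the list alone. CREM, a transcription factor that cyclic AMP induces, fell by 1.29 ± 0.19 (2.45-fold, adjusted p = 4.0e-07, lower in 40 of 44 donors). The orphan nuclear receptors NR4A3 and NR4A2 fell by 1.40 ± 0.28 and 1.17 ± 0.20, and the phosphodiesterase PDE4B, which breaks down cyclic AMP, fell by 1.02 ± 0.17 (lower in 39 of 44). NR4A3 was well above background on only 25 of 44 severe and 33 of 38 control arrays, so the size of its change is uncertain. The cytokine OSM fell by 1.37 ± 0.23, the growth factors AREG and VEGFA by 1.31 ± 0.29 and 0.91 ± 0.22, and the AP-1 subunit FOSL2 by 0.95 ± 0.14. ZNF331, a zinc finger gene outside the lists, had the largest decrease among the named genes that passed, 1.59 ± 0.19 (3.02-fold, adjusted p = 3.7e-10). It was below the control median in 42 of 44 donors.

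**Figure D1:**
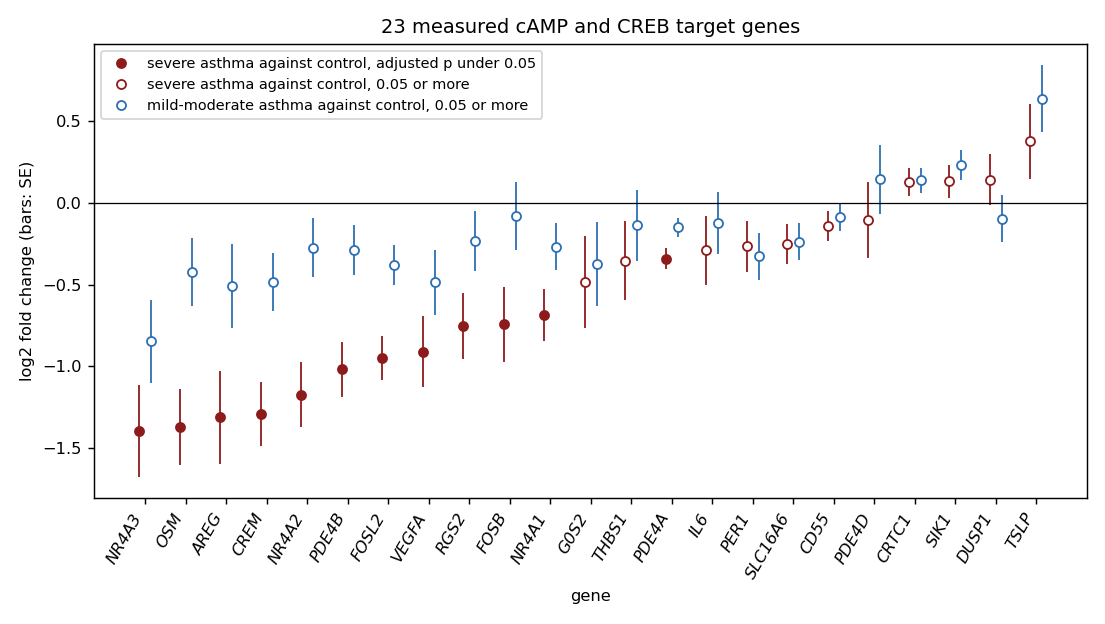
Log2 fold change against control (y axis, bars are 1 SE) of the 23 measured members of the cyclic AMP and CREB target list (x axis). Values are for severe (n = 44) and mild-moderate asthma (n = 72), both against 38 controls, with filled symbols at an adjusted p under 0.05. In severe asthma 12 members passed, all of them lower, and in mild-moderate asthma 0 passed.

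The cyclic AMP list had an adjusted p of 0.000585 by permutation over the donors and an adjusted p = 0.0341 with an estimated correlation between genes. With the scan campaign as a block the shift was -0.56 (adjusted p = 0.000585, in a range from 0.00029 to 0.0035 over 14 alternatives that all kept the call), and within campaigns 1, 2 and 3 it was -0.74, -0.60 and -0.34. ZNF331 changed by -1.45, -1.64 and -1.64, and CREM by -2.01, -1.07 and -1.05, within the campaigns. Of the 23 members 10 also belong to another list. With normexp background and quantile normalization NR4A3 changed by -0.53 and NR4A2 by -0.84, and both calls were kept. CREM has 4 tested probes, with changes from -1.67 to -0.06, of which 3 passed.

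Glucocorticoid-induced genes shifted upward in severe asthma, by 0.27 ± 0.08 (adjusted p = 0.0202, 32 of 44 donors above the control median). Of 21 members 6 rose and 2 fell, and 9 rose and 2 fell when adjusted over the list alone. ZBTB16, a transcription factor strongly induced by steroids, rose by 1.10 ± 0.20 (2.14-fold, adjusted p = 3.7e-05, 36 of 44), the decoy receptor IL1R2 by 1.24 ± 0.27, the stress regulator DDIT4 by 0.67 ± 0.15 and KLF9 by 0.56 ± 0.10 (38 of 44). FKBP5, a chaperone that limits the glucocorticoid receptor, rose by 0.45 ± 0.14 (adjusted p = 0.0437, 27 of 44), and its call was lost in 11 of 17 alternatives. The call of DDIT4 ended without 18 arrays that correlated poorly with the rest and without the third campaign. RGS2 and SLA were the members that fell. The shift was 0.27 with the campaign as a block (adjusted p = 0.0179) and 0.15, 0.25 and 0.40 within the campaigns. The list gave an adjusted p = 0.393 with an estimated correlation, and over 14 alternatives it lay between 0.15 and 0.49, with 8 keeping the call and an adjusted p from 0.00029 to 0.239. The alternatives that ended its call included the 4 cell marker means as covariates (adjusted p = 0.228 by permutation).

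Genes of the NRF2 antioxidant and xenobiotic response also shifted upward, by 0.27 ± 0.07 (adjusted p = 0.00515, 34 of 44 donors). Of 13 members 3 rose, GCLC and GCLM, the subunits of the enzyme that limits glutathione synthesis, by 0.41 ± 0.10 and 0.28 ± 0.08, and TIPARP, an aryl hydrocarbon receptor target, by 0.28 ± 0.08. Adjusted over the list alone, 4 rose and 1 fell. The list gave an adjusted p = 0.243 with an estimated correlation, a value of 0.27 with the campaign as a block (adjusted p = 0.0111), and 0.44, 0.15 and 0.34 within the campaigns. It ranged from 0.10 to 0.27 over 14 alternatives, and the call ended with 4 cell marker means as covariates (adjusted p = 0.224, in a range from 0.00088 to 0.224), without the 18 arrays of low correlation, with the scan day as a block and without the third campaign. GCLC kept its call in 15, GCLM in 12 and TIPARP in 16 of 17 alternatives.

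A signature of type 2 airway inflammation, built from genes that interleukin-13 induces in epithelium and from mast cell genes, shifted by 0.46 ± 0.14 (adjusted p = 0.0170, 31 of 44 donors). Only the mast cell carboxypeptidase CPA3 rose by itself among its 15 members (0.88 ± 0.25, adjusted p = 0.0212, 33 of 44), and 6 rose when adjusted over the list alone. CPA3 kept its call in 13 of 17 alternatives and changed by 0.50 without the 18 arrays of low correlation (adjusted p = 0.314, in a range from 0.00365 to 0.314). The shift was 0.45 with the campaign as a block (adjusted p = 0.0179) and 0.54, 0.47 and 0.36 within the campaigns. The list gave an adjusted p = 0.431 with an estimated correlation, and it kept its call in 8 of 14 alternatives, with values from 0.19 to 0.49 and an adjusted p from 0.0072 to 0.370. The call ended with the 4 cell marker means, pan-epithelial markers among them, as covariates (adjusted p = 0.247 by permutation). The shift was thus not separated from the share of epithelial and other marked cells. IL4R, the receptor chain shared by interleukins 4 and 13, fell by 0.45 ± 0.07 (adjusted p = 5.8e-07, 36 of 44).

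Markers of other cells were compared beside these groups. Pan-epithelial markers differed by 0.52 ± 0.21 (adjusted p = 0.0984), with 0.86, 0.12 and 0.94 within the campaigns, neutrophil markers by 0.35 ± 0.14 (adjusted p = 0.0790), erythroid markers by 1.13 ± 0.43 (adjusted p = 0.0790), eosinophil markers by 0.21 ± 0.11 (adjusted p = 0.181) and T cell markers by -0.22 ± 0.24 (adjusted p = 0.654), and none of these lists passed. Within the campaigns neutrophil markers differed by 0.02, 0.36 and 0.55, erythroid markers by 0.64, 1.07 and 1.54, and T cell markers by -0.69, 0.07 and -0.32. Alveolar macrophage markers differed by -0.10 ± 0.06 (adjusted p = 0.270). Among single genes, KRT18, a keratin of simple epithelium, rose by 0.79 ± 0.18, the mucosal genes TFF3, CEACAM6 and BPIFB1 by 1.55 ± 0.39, 1.27 ± 0.33 and 1.38 ± 0.40, and KRT23 by 1.67 ± 0.32 (38 of 44 donors). SCGB1A1, the club cell secretoglobin, fell by 1.29 ± 0.36 (adjusted p = 0.0204, 32 of 44), with -0.15, -2.21 and -0.60 within the campaigns. The erythroid heme enzyme ALAS2 rose by 1.83 ± 0.50, the platelet chemokine PPBP by 1.53 ± 0.48 and the neutrophil defensin DEFA3, nearly identical to its gene copies on the array, by 1.96 ± 0.46. DEFA3 was well above background on 33 of 44 severe and 24 of 38 control arrays, and changed by 0.37, 1.67 and 3.61 within the campaigns. KRT1 was well above background on 27 of 44 severe and 11 of 38 control arrays and passed as higher (adjusted p = 0.00448), and no size is given for its change. Of these epithelial and blood cell genes KRT23 kept its call in all 17 alternatives. Without the 18 arrays of low correlation KRT18 changed by 0.40, CEACAM6 by 0.75 and BPIFB1 by 0.88, and these calls ended. PPBP kept its call in 6 of 17 alternatives.

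In all, limma called 546 of 14479 genes at an adjusted p under 0.05, 185 higher and 361 lower in severe asthma, of which 49 differed at least 2-fold. The authors' processed values gave 320 higher and 321 lower. Without 1 array of the closest pair of severe arrays 437 genes passed, 127 higher and 310 lower. All of the 8 largest increases and 8 largest decreases kept their sign in the 3 campaigns and their call with the campaign as a block. Without the 18 arrays of low correlation, of which 9 were severe, 8 mild-moderate and 1 control, 10 of those 16 lost the call, and DEFA3, ALAS2, KRT1, TFF3, PPBP, PSCA, HEMGN and FBN1 were among them, as were the near-identical elastase genes CELA2A and CELA2B. In all, 33 of 65 calls of named genes ended without these arrays. The values of TFF3 and PSCA then were 1.00 and 0.83, against 1.55 and 1.49.

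**Figure D2:**
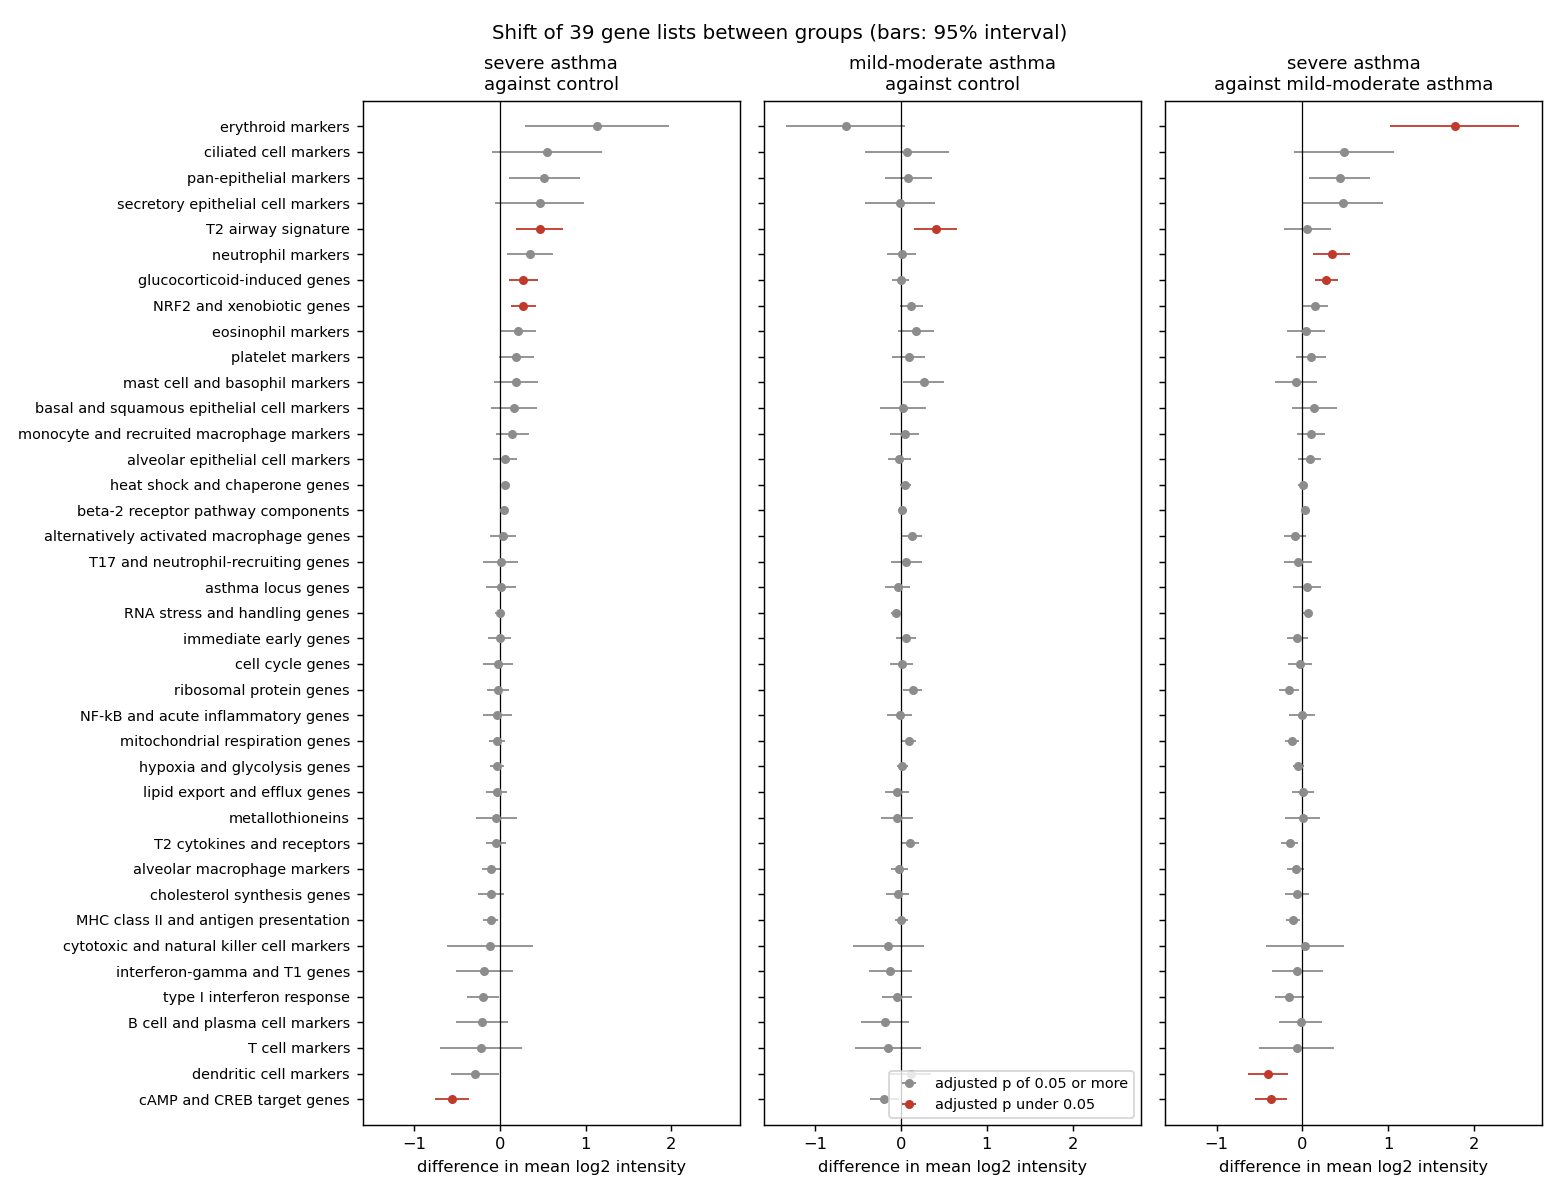
Mean log2 difference of the 39 gene lists (x axis, with 95% intervals) in the 3 comparisons, one panel each, with lists at an adjusted p under 0.05 in red. In severe asthma against control 4 lists passed, in mild-moderate asthma against control 1, and in severe against mild-moderate asthma 5.

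Mild-moderate asthma was set against the same controls to ask which differences were present without severe disease. Among the named genes that passed, the secretoglobins SCGB1A1 and SCGB3A1 had the largest decreases. SCGB1A1 fell by 1.43 ± 0.33 (2.69-fold, adjusted p = 0.00639, lower in 58 of 72 donors, n = 72 and 38), and SCGB3A1 by 1.35 ± 0.36 (60 of 72). The list of 17 measured secretory epithelial markers did not pass and differed by -0.01 ± 0.21 (adjusted p = 0.979, 2 members lower), with a median member at 0.23, opposite in sign, and by -0.22, -0.29 and 0.44 within the campaigns. The elastase genes CELA2B and CELA2A, which the array may not separate, fell by 1.32 ± 0.36 and 1.28 ± 0.33. RGL3, a Ras effector, fell by 0.67 ± 0.13 (adjusted p = 0.000975, 65 of 72), the unconventional myosin MYO7B by 0.66 ± 0.13 and RCN3, a calcium-binding protein of the endoplasmic reticulum, by 0.65 ± 0.13. Over 17 alternatives MYO7B ranged from -0.66 to -0.29 and RCN3 from -0.65 to -0.31, and the call of MYO7B ended without the third campaign. With the scan day as a block SCGB1A1 and SCGB3A1 changed by -1.29 and -1.17, and the calls of both secretoglobins and both elastase genes ended (SCGB1A1 adjusted p = 0.0535, in a range from 0.000411 to 0.0535). Because the controls are shared, the changes of SCGB1A1 in both asthma groups are not independent of each other.

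The type 2 airway signature was the 1 list of 39 that passed, with a shift of 0.40 ± 0.13 (adjusted p = 0.0246, 50 of 72 donors above the control median). CLCA1, a goblet cell protein that interleukin-13 induces, was its 1 member of 15 to rise (adjusted p = 0.0420), and 4 rose when adjusted over the list alone. CLCA1 was well above background on 24 of 72 mild-moderate and only 2 of 38 control arrays, so no size is given for its change, and its call held in 3 of 16 alternatives (adjusted p from 0.0224 to 0.250). With the campaign as a block the list's shift was 0.33 and its call ended (adjusted p = 0.0625, in a range from 0.0082 to 0.376 over 14 alternatives), and within the campaigns it was 0.06, 0.34 and 0.52. The list gave an adjusted p = 0.431 with an estimated correlation. Eosinophil markers differed by 0.17 ± 0.11 (adjusted p = 0.315) and mast cell and basophil markers by 0.26 ± 0.12 (adjusted p = 0.163).

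The cyclic AMP list differed by -0.19 ± 0.09 in mild-moderate asthma (adjusted p = 0.134) with 0 of 23 members past the test by limma, and 2 rose and 5 fell when adjusted over the list alone. Glucocorticoid-induced genes differed by -0.0054 ± 0.05. Pan-epithelial markers differed by 0.08 ± 0.14, T cell markers by -0.15 ± 0.20, neutrophil markers by 0.0071 ± 0.09, with a median member at -0.016, and erythroid markers by -0.65 ± 0.35 (adjusted p = 0.236). Within the campaigns pan-epithelial markers differed by -0.02, -0.18 and 0.51, and erythroid markers by -1.57, -0.45 and -0.53. AGER, a marker of type 1 alveolar epithelial cells, fell by 0.34 ± 0.09, the B cell gene FCRL1 by 0.57 ± 0.15 and the stress gene SESN2 by 0.40 ± 0.11. FCRL1 ranged from -0.61 to -0.30 over 17 alternatives, and its call ended with the slide as a block and without the third campaign. With the scan day as a block the calls of AGER and SESN2 ended, and that of AGER also with the authors' values without 5 columns. Among the increases were CDC42EP3, an effector of the GTPase CDC42 (0.41 ± 0.09), the purinergic receptor P2RY13 (0.41 ± 0.11) and the histone H4 genes H4C1, H4C6 and H4C8 (0.72 ± 0.18, 0.47 ± 0.13 and 0.38 ± 0.11), whose copies have closely similar sequences. The calls of GPC4, H4C6, H4C8 and CLCA1 ended with the campaign as a block and without the 18 arrays of low correlation, and H4C8 changed by -0.14, 0.26 and 0.70 within the campaigns. The call of H4C1 ended with the replicate block and without the third campaign, with a lowest value of 0.26 over 17 alternatives. P2RY13 kept its call in 13 of 17.

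By limma 169 genes passed, 23 higher and 146 lower in mild-moderate asthma, of which 5 differed at least 2-fold. At an unadjusted p under 0.05 there were 1748. With the campaign as a block 211 passed, 33 higher and 178 lower. The balance of directions was more even in other alternatives, with 103 higher and 172 lower without the 18 arrays of low correlation, 102 and 111 without the third campaign, and 406 and 431 with array weights. Within campaign 1 alone 86 were higher and 76 lower, and within campaigns 2 and 3 limma called 0 genes, with 1164 and 1446 at an unadjusted p under 0.05.

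Severe and mild-moderate asthma were set against each other to ask what set severe disease apart among donors with asthma. Erythroid genes had the largest increases in severe asthma among the named genes that passed. Their list shifted by 1.78 ± 0.38 (SE, n = 44 and 72, 95% interval 1.03 to 2.53), and 33 of 44 severe donors lay above the mild-moderate median. Of 11 members 8 rose and none fell, and 10 rose when adjusted over the list alone. The globin genes HBA2 and HBA1, whose transcripts are nearly identical, rose by 3.26 ± 0.67 and 3.15 ± 0.64, HBB by 2.70 ± 0.62 (6.49-fold, 35 of 44 donors) and HBD by 3.05 ± 0.65, and ALAS2 rose by 2.17 ± 0.43 (4.49-fold, adjusted p = 0.000492, 37 of 44). The spread was wide in both groups, with HBB at 7.08 ± 3.26 (SD) in severe and 4.38 ± 3.44 in mild-moderate asthma. Against control, HBA2 and HBB differed by 1.45 and 1.17 in severe asthma, and by -1.81 and -1.53 in mild-moderate asthma. By limma none of these changes passed. Of 9 globin genes 2, HBM and HBQ1, passed as higher in severe asthma than in control. Lower values in mild-moderate asthma thus made up part of the difference between the asthma groups. The list had an adjusted p of 0.000585 and an adjusted p = 0.130 with an estimated correlation, and with the campaign as a block it shifted by 1.86 (adjusted p = 0.00078, in a range from 0.00029 to 0.0798) and within the campaigns by 2.21, 1.52 and 2.07. With the scan day as a block the list shifted by 1.37, HBA2 changed by 2.61 and HBB by 2.14, and the list and HBA2, HBA1, HBD and HBB lost the call (HBB adjusted p = 0.102, in a range from 0.00171 to 0.102).

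Glucocorticoid-induced genes shifted by 0.28 ± 0.07 (adjusted p = 0.00195, 34 of 44 severe donors), with 5 of 21 members higher and 1 lower, or 8 and 2 when adjusted over the list alone. ZBTB16 rose by 1.18 ± 0.17 (adjusted p = 9.5e-07, 37 of 44), DDIT4 by 0.81 ± 0.13, KLF9 by 0.51 ± 0.09 and FKBP5 by 0.53 ± 0.12. The cyclic AMP list fell by 0.37 ± 0.09 (adjusted p = 0.00468, 35 of 44), with 8 of 23 members lower, or 12 when adjusted over the list alone. NR4A2 fell by 0.90 ± 0.17, CREM by 0.81 ± 0.17, PDE4B by 0.73 ± 0.15 and FOSL2 by 0.57 ± 0.12. With the campaign as a block the glucocorticoid list shifted by 0.29 (adjusted p = 0.000585, in a range from 0.00029 to 0.0731 over 14 alternatives) and the cyclic AMP list by -0.35 (adjusted p = 0.00936, in a range from 0.0012 to 0.0844). The former call ended without the 18 arrays of low correlation and with the 4 cell marker means as covariates, and the latter with the scan day as a block and without the third campaign. Within the campaigns they shifted by 0.27, 0.27 and 0.33, and by -0.49, -0.27 and -0.36. The glucocorticoid list gave an adjusted p = 0.243 with an estimated correlation, and the cyclic AMP list an adjusted p = 0.393 with an estimated correlation.

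Dendritic cell markers fell by 0.40 ± 0.12 (adjusted p = 0.0171, 30 of 44 severe donors below the mild-moderate median). Of 14 members 7 fell and none rose, and 8 fell when adjusted over the list alone. CD1E, CD1C and CD1B, which present lipid antigens, fell by 0.78 ± 0.19, 0.70 ± 0.19 and 0.81 ± 0.24, and the IgE receptor chain FCER1A fell by 0.71 ± 0.20. The list shifted by -0.41 with the campaign as a block (adjusted p = 0.0155, in a range from 0.0068 to 0.132) and by -0.20, -0.43 and -0.51 within the campaigns, and it gave an adjusted p = 0.609 with an estimated correlation. Its call ended without the 18 arrays of low correlation and without the third campaign. Against control the list differed by -0.29 ± 0.14 in severe asthma (adjusted p = 0.181 by permutation). In mild-moderate asthma it differed from control by 0.11 ± 0.12 (adjusted p = 0.654), and neither passed. Of its 14 members 5 also belong to another list. CD1B was well above background on 22 of 44 severe and 46 of 72 mild-moderate arrays and changed by -0.17 with normexp background and quantile normalization, 1 of 6 among 17 alternatives that ended its call (adjusted p from 0.0124 to 0.169).

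Neutrophil markers rose by 0.34 ± 0.11 (adjusted p = 0.0239, 33 of 44 donors), with 5 of 16 members higher, or 8 higher and 1 lower when adjusted over the list alone. PROK2, a chemokine-like peptide of neutrophils, rose by 0.91 ± 0.29, the potassium channel KCNJ15 by 0.75 ± 0.22, alkaline phosphatase ALPL by 0.66 ± 0.19 and the membrane protease MMP25 by 0.59 ± 0.18. The calls of these 4 genes all ended with the scan day as a block and without the 18 arrays of low correlation, where their values were 0.67, 0.59, 0.17 and 0.33. The list shifted by 0.38 with the campaign as a block (adjusted p = 0.00936) and by 0.35, 0.35 and 0.44 within the campaigns, with an adjusted p = 0.431 for an estimated correlation. It kept its call in 8 of 13 alternatives, with values from 0.16 to 0.47 and an adjusted p from 0.0094 to 0.338, and leaving out 1 severe array of a closely similar pair gave an adjusted p of 0.0547. Pan-epithelial markers differed beside it by 0.43 ± 0.18 (adjusted p = 0.0997), eosinophil markers by 0.04 ± 0.11 and T cell markers by -0.07 ± 0.22.

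By limma 868 genes passed, 285 higher and 583 lower in severe asthma, of which 26 differed at least 2-fold. The authors' processed values gave 545 higher and 287 lower. Without 1 array of the closest pair of severe arrays 581 genes passed, 190 higher and 391 lower. The deviations of these 2 arrays from the gene means correlated at 0.955, against 0.844 for the next closest pair. Whether both came from 1 donor was not tested. The largest decreases included PTGER3, a prostaglandin E receptor (-1.10 ± 0.24, and -0.43 with normexp background and quantile normalization), the stress kinase PLK2 (-1.04 ± 0.17, lower in 36 of 44 donors), ZNF331 (-1.02 ± 0.17, 39 of 44), OSM (-0.95 ± 0.20) and the growth factor EREG (-0.95 ± 0.22). EREG ranged from -1.13 to -0.59 over 17 alternatives, and its call ended with the scan day as a block. Further changes among genes with bright signals were smaller, such as the hexokinase HK2 (-0.34 ± 0.06) and the antigen-loading gene HLA-DMB (-0.23 ± 0.06). All of the 16 largest changes kept their sign in the 3 campaigns, and LZTS1, well above background on 14 of 44 severe arrays and with a call kept in 3 of 17 alternatives, alone lost it with the campaign as a block. Without the 18 arrays of low correlation 38 genes passed as higher and 116 as lower, and 38 of 72 calls of named genes ended, those of PTGER3, LZTS1, HBG1 and HLA-DMB among them. FOXJ1, KRT5, FABP4, CD3D, GNLY, CSF3R, CLC, CXCL10, IFI44L and IL1B, markers of cell types and of interferon and inflammatory responses fixed in advance, passed in none of the 3 comparisons.

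**Figure D3:**
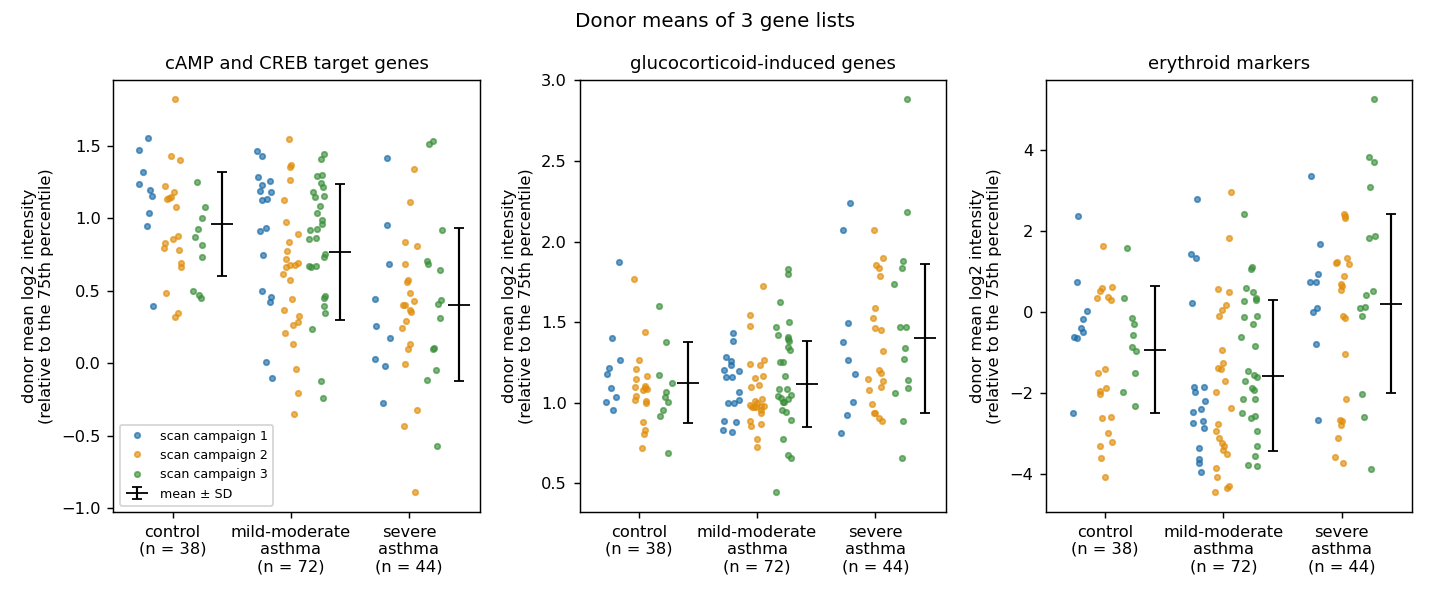
Mean log2 level of each donor (points, coloured by scan campaign) over the cyclic AMP, glucocorticoid-induced and erythroid lists (y axis) in controls (n = 38), mild-moderate (n = 72) and severe asthma (n = 44), with bars for the mean ± SD. Severe donors lay 0.56 lower than controls in the first list on average, and 0.28 and 1.78 higher than mild-moderate donors in the others, with wide overlap of single donors.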

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

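The tests of immediate early genes, of platelet chemokines and neutrophils and of other splits of the donors were chosen only after the result was seen. For 5 gene lists the change against control differed between severe and mild-moderate asthma, tested as the difference between these 2 groups. The differences were -0.37 for cyclic AMP and CREB targets, 1.78 for erythroid markers, 0.28 for glucocorticoid-induced genes, -0.40 for dendritic cell markers and 0.34 for neutrophil markers, on the log2 scale. By camera with an estimated correlation between genes their adjusted p lay between 0.130 and 0.609, above the threshold of 0.05. The differences of the glucocorticoid, dendritic and neutrophil lists are given as values only.

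Cyclic AMP and CREB target genes were lower in severe asthma than in control. The shift was -0.556 with the scan campaign as a block, so the campaign does not account for it. With dendritic, mast and T cell marker means as covariates it was -0.555 (95% interval -0.753 to -0.357, p = 1e-05, the smallest the permutations can give). These marker means thus do not account for it either. Their lists differed by -0.29, 0.19 and -0.22 in this comparison and none passed. The labels give no cell counts, so cell shares that these means do not follow stay untested. General activation of cells during handling stays open. The 18 immediate early genes measured, of which 4 are also cyclic AMP targets, shifted by -0.0015 (95% interval -0.133 to 0.130, p = 0.982), but 3 of them rose and 3 fell, so their mean decides nothing. A change within the macrophages themselves stays open too, as does an exposure such as medication that the labels do not give, and neither was tested.

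Erythroid genes were higher in severe than in mild-moderate asthma. A few lavages that held blood would raise the mean more than the median, but the group medians differed by 2.43 (p = 0.00017), above the bound of 0.889 set from the difference between means. The shift was 1.86 with the scan campaign as a block. Blood in many of the lavages stays open. Over 116 severe and mild-moderate donors, with group means removed, the erythroid mean rose with the neutrophil mean (r = 0.568, 95% interval 0.43 to 0.68, p = 1e-05, rho = 0.482, and r = 0.512 without the 2 farthest donors, adjusted p = 0.00012 over 24 relations), also within the campaigns (0.582, 0.460 and 0.612), and neutrophil markers rose in the same comparison. It did not follow the mean of the platelet chemokines PF4 and PPBP (r = 0.018, 95% interval -0.16 to 0.20, p = 0.849) or of all 7 platelet markers (r = -0.0152, 95% interval -0.20 to 0.17, p = 0.874). Yet PF4 rose by 0.53 ± 0.16, with its call kept in 9 of 17 alternatives, while GNG11 differed by -0.73 ± 0.32, so the platelet mean mixes members that move apart. Over all arrays the erythroid and neutrophil means also both followed the first principal component, which held 19.8% of the variance (r = -0.535 and -0.528). Pan-epithelial markers followed it more closely (r = -0.910), so the relation of erythroid and neutrophil means may not be particular to these cells. Whole blood and a separate gain of red cells and neutrophils cannot be told apart from these values.

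The split of the donors into their groups was compared with other splits of the same sizes. In each comparison 1 of 100 splits, the real one, gave as many genes, so a random split of these sizes rarely gives such counts. The other splits ignored campaign, scan day and slide, so they do not test an uneven spread of the groups over these. The real counts were 546, 169 and 868 for severe against control, mild-moderate against control and severe against mild-moderate, and the highest of the other splits gave 1, 4 and 6.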

How the results depend on the processing

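The alternatives without campaign 3, without 1 array of the closest pair or without 5 columns of the authors' table, and with campaign and detected probes as covariates, were chosen after seeing the data. Over up to 17 alternatives that give values of genes, calls of named genes were kept 2116 times and lost 528 times. The losses include genes that belong to a list whose mean is 1 of the 4 marker covariates, which removes their change by construction. Over up to 14 alternatives of the list test, camera left out, calls of lists were kept 104 times and lost 35 times, some calls of genes and 31 of lists were gained, and none reversed. Counts of changed genes and of lists stayed within 1.5 times of the main ones 71 times and moved 34 times. As shares of the genes tested, the main counts were 3.77% (severe against control), 1.17% (mild-moderate against control) and 5.99% (severe against mild-moderate). Without the 18 low-correlation arrays these were 1.90%, 1.90% and 1.06%, and at a 1.5-fold minimum 1.06%, 0.104% and 0.808%. Severe against control gave 2.31% without campaign 3. Mild-moderate against control gave 1.98% with the authors' values, 0.698% with the scan day as a block and 5.78% with array weights. Severe against mild-moderate gave 2.77% with 4 marker covariates and 1.00% with the scan day as a block. The replicate block gave 3.33%, 9.86% and 20.5%, but the numbers do not pair donors: 120 pairs of the same number had a median correlation of deviations of 0.0016, and 44 exceeded 0.1. The lists that passed, 4, 1 and 5 in the same order, became 2, 0 and 3 without the low-correlation arrays, 1, 0 and 2 without campaign 3, 13, 5 and 12 by camera with a preset and 1, 0 and 0 with an estimated correlation. With the scan day as a block 1 list passed in severe against control and 2 in severe against mild-moderate. In mild-moderate against control 0 lists passed the permutation test with normexp background and quantile normalization, the stricter filter or the campaign as a block, and 2 with the authors' values. Without their 5 columns 3 passed there and 9 in severe against mild-moderate. A fold minimum lowers a count by construction, and for the rest the cause was not tested. The slide block, array weights, every probe and only 2 groups were run for genes and not for lists. Signal over background limits dim genes most in campaign 3, with a median of 25699 probes detected.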

Other observations

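The gene groups of the first paragraph and the tests of epithelial and secretory markers were chosen only after the result was seen. The groups were picked for members that had changed, so they are given as values without a p. In severe asthma against control the EGF receptor ligands AREG, EREG and HBEGF fell by 1.31, by 1.08 ± 0.26 and by 0.96 ± 0.16. Other ligands of the receptor were not among the genes tested, so nothing is said of the family. Receptors of prostaglandin E moved apart in severe asthma against control, where PTGER3, which lowers cyclic AMP, fell by 1.44 ± 0.28 (range over 17 alternatives -1.47 to -0.54, well above background on 29 of 44 severe arrays). Of the receptors that raise cyclic AMP, PTGER4 fell by 0.39 ± 0.09 and PTGER2 rose by 0.56 ± 0.16. The mean of the CD1 molecules differed by -0.59 ± 0.16 in severe against mild-moderate asthma (3 of 5 lower), and by -0.60 with the campaign as a block. Against control it differed by -0.33 ± 0.19 in severe and 0.26 ± 0.16 in mild-moderate asthma, with no member called. The mean of histone genes differed by 0.20 ± 0.07 in mild-moderate asthma against control (3 of 56 higher), and by 0.15 with the campaign as a block.

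Genes of stress and handling went both ways in severe asthma against control. GADD45B rose by 0.67 ± 0.11 (40 of 44 donors), while SESN2, GADD45A and the endoplasmic reticulum gene HERPUD1 fell by 0.71 ± 0.12, 0.58 ± 0.12 and 0.40 ± 0.08. Immediate early genes did so too, with MYC higher by 0.61 ± 0.13 and KLF6 by 0.35 ± 0.09, and NR4A1 lower (-0.68 ± 0.16).

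SCGB1A1 was lower than control in both asthma groups, which share their controls. Fewer epithelial cells in the lavage would have lowered pan-epithelial markers by about as much, but these differed by 0.085 in mild-moderate asthma against control (95% interval -0.192 to 0.362). With the scan campaign as a block the smaller of both changes was -1.30 (adjusted p = 0.0178, in a range from 0.00026 to 0.0999 over 17 alternatives). Fewer secretory cells of every kind would have lowered the 17 measured secretory markers, SCGB1A1 among them, but these differed by -0.0116 in mild-moderate asthma (95% interval -0.418 to 0.395, with a median member at 0.23, opposite in sign) and by 0.47 in severe asthma against control (95% interval -0.05 to 0.99). The source of the decrease stays open.

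A shared exposure could raise glucocorticoid-induced genes and lower cyclic AMP targets in the same donors. It predicts a negative correlation of both list means, without shared members, over severe donors. Over 44 donors r was 0.24 (95% interval -0.06 to 0.50, p = 0.112, rho = 0.192 with p = 0.212, and r = 0.06 without the 2 farthest donors), with an adjusted p of 0.447 over 24 relations and values of 0.457, 0.104 and 0.275 within the campaigns. Over 72 mild-moderate donors r was negative, -0.163 (95% interval -0.38 to 0.07, p = 0.172, adjusted p = 0.589), with -0.542 (unadjusted p = 0.0238, adjusted p = 0.114), -0.0384 and -0.185 within the campaigns, and over 38 controls it was 0.193. The interval over severe donors argues against a clearly negative relation among them, where both lists had shifted, and an exposure of equal strength in all severe donors would leave no such relation.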
